A study of Mus musculus with 6 samples.

How the data were processed

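The data are RNA-seq profiles of primary cultures of mesenchymal cells, the connective tissue and muscle-lineage cells under the gut epithelium, from the small intestine of C57 mice. Per the labels' protocols, 3 cultures came from embryos at embryonic day 14.5 (E14.5) and 3 from adults. The adult gut was opened and its villi scraped off, whereas the embryonic gut was cut into pieces. In both, the epithelium was removed by chelation, the remaining tissue was digested with collagenase and dispase, and the cells were grown to confluence in serum. RNA was taken at passage 2 to 3. Stranded libraries from poly(A) RNA were read from a single end over 75 bp on an Illumina NextSeq 500. The handling of the tissue before digestion therefore differed between the groups, and no sort or gate was named that would remove other cell types.

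The authors deposited whole-number read counts per gene, without normalization, in 1 table per library. Per the submitters' processing notes, reads were aligned with STAR to mm10. The STAR version, the annotation and the rule for reads shared between genes are not given in the sources used here. Each table holds 3 count columns, for unstranded, forward-strand and reverse-strand counting. The reverse-strand column was used, because forward-strand counts made up only 1.33% to 1.69% of all stranded gene counts. Rows for unmapped, multimapping, unassigned and ambiguous reads took 17.45% to 19.81% of all counted reads per library and were left out of library sizes and tests. Reads that map to several places are not in the gene rows, so genes with near-identical copies, such as ribosomal protein genes and their pseudogenes, are measured with some uncertainty. None of the 13 mitochondrially encoded genes of a prepared list has a row, so mitochondrial RNA was not analysed here.

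The tables name 23329 genes by symbol. Gene totals ranged from 18850224 counts in adult replicate 2 to 32672370 in E14.5 replicate 1. Replicates were numbered in accession order within each group. The labels do not say whether the 3 cultures of a group came from separate animals or litters. The number at the end of a title is shared by 2 of the 3 libraries of each group and missing from the other, so it does not number replicates. The names of all 6 deposited tables also hold the letters PBS, which the labels do not explain, and whether the cultures shared a treatment is not given in the sources used here. The p-values therefore measure the spread between these cultures. Sample titles begin with 1 of 3 prefixes, each carried by 1 E14.5 and 1 adult library, and the labels do not say what a prefix marks. The groups, the tests, 40 gene lists, the rule for naming genes and the alternatives were set before the data were examined, except for the alternatives said below to have been added later.

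Differential expression was tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group, which left 13478, and scaled by TMM. The quasi-likelihood test with robust dispersion estimation compared E14.5 with adult, with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p-values for single genes come from this test unless another tool is named. Fold changes are E14.5 over adult. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of the F statistic, which is approximate. Levels are CPM, counts scaled to a common library total, on TMM-scaled library sizes, computed here from the deposited counts and given as mean ± SD over 3 libraries. Where a group had no counts, a fold was bounded with a floor of 3 counts per library, which covers counting error only.

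Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, two-sided, adjusted over the 38 lists with at least 3 tested members. The same test with the correlation estimated from the data, and the self-contained fry test, were alternatives. The rule for named genes took Dlk1, which the series title names. It then took the 10 largest changes in each direction among genes past the threshold, at least 2-fold changed, with a mean of at least 10 CPM in the higher group and no overlap between groups, leaving out unnamed gene models. From each list it took up to 3 higher and 3 lower members past the threshold and the 2 most abundant members not past it. Some genes that the rule took are not reported here.

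The other alternatives were DESeq2 size factors, upper-quartile scaling, library size alone, no filter, a stricter filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a test against a 2-fold threshold, an adjusted p of 0.01, the title prefix as a block, and each library left out in turn. Of those added after the data were seen, 1 used the unstranded column, 1 left out adult replicate 2 with E14.5 replicate 3, and 1 left out adult replicates 2 and 3.

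The steps were tested on counts simulated for the 13478 genes of this comparison with 200 genes changed per draw, in 3 draws. The edgeR test recovered 18.0% of 150 genes changed 2-fold, 68.0% of those changed 4-fold, 80.7% of those changed 8-fold and 90.7% of those changed 16-fold. Of its 416 calls, 7.21% were false, against 31.6% of 678 calls by DESeq2 and 6.84% of 395 calls by limma-voom. Camera called the 1 shifted list in all 3 draws and 1 of 111 unchanged lists. Genes were drawn independently, so these draws do not test camera where the members of a list vary together. The inter-gene correlation estimated from the real data ran from -0.13 for enteric neuron markers to 0.86 for genes of S phase and mitosis.

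Gene coordinates come from GENCODE release M21 on the same mouse build, 1-based. The submitters' annotation may differ from it. Of the 23329 symbols, 22857 were matched, older symbols through RefSeq synonyms. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15, adding 0.1 CPM where an axis is logarithmic.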

Results

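Gene expression was measured in cultured mesenchymal cells from the small intestine of E14.5 mouse embryos (3 cultures) and adult mice (3 cultures). Counts assigned to genes came to 32672370, 32140016 and 30430596 in E14.5 replicates 1, 2 and 3, and to 28094847, 18850224 and 29903594 in adult replicates 1, 2 and 3. Adult replicate 2 was therefore the least precisely measured library. The gene with the most counts, which also scale with transcript length, was Fn1, which encodes fibronectin, in all 3 E14.5 libraries and Thbs1, which encodes thrombospondin 1, in all 3 adult libraries. The first principal component of log2 CPM took 54.9% of the variance and separated the groups. The other axis, with 20.8%, spread the libraries within each group, from -58.29 for E14.5 replicate 2 to 40.74 for E14.5 replicate 3. The median SD of log2 CPM between cultures was 0.295 for E14.5 and 0.194 for adults.

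**Figure D1:**
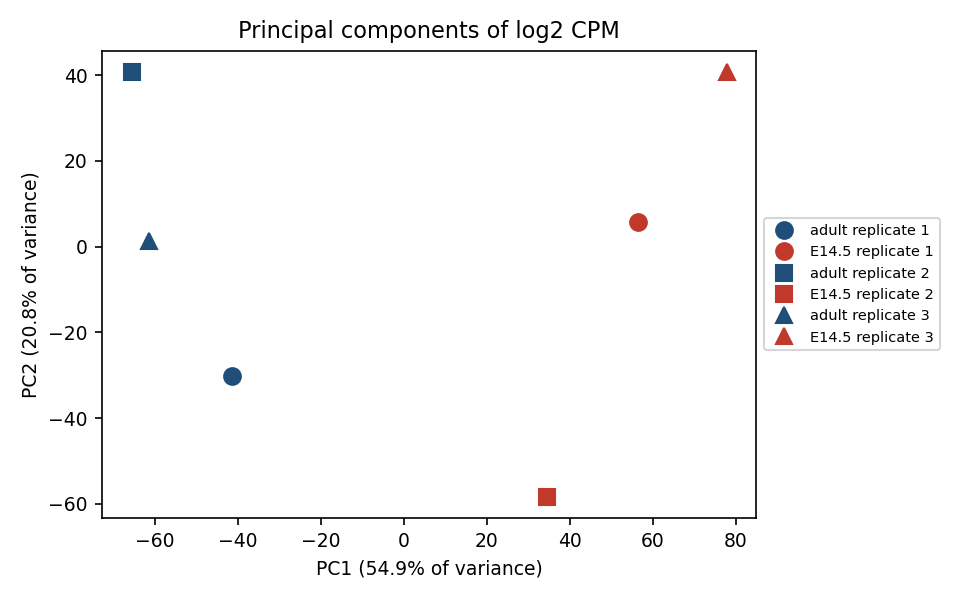
Principal components of log2 CPM over 13478 genes, with the share of variance on each axis. Each point is 1 library, coloured by group, and the 3 E14.5 libraries lie between 34.39 and 77.83 on the first axis, to the right of all adult libraries.

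The series title names stromal Dlk1, and the comparison asks which genes differ between embryonic and adult mesenchyme. Dlk1, an imprinted gene for a transmembrane protein related to the Notch ligands, was far higher in the embryonic cultures. Its level was 261, 56.7 and 350 CPM in the E14.5 libraries and 3.597, 2.632 and 2.672 CPM in the adult libraries. The log2 fold change was 6.23 (SE 0.76, adjusted p = 0.034, edgeR), a 74.9-fold difference. The gene lies on chromosome 12 of mm10 from 109452823 to 109463336 on the plus strand. The study may have chosen Dlk1 on these samples, so its difference is not independent evidence. Between the libraries that share a title prefix, its log2 difference was 6.156, 4.394 and 6.997. The log2 fold change stayed between 5.66 and 6.68 under all alternatives tried. However, adjusted p rose to 0.090 without adult replicate 1, 0.112 without E14.5 replicate 1, 0.092 without adult replicate 2 and 0.181 without adult replicate 3. It also rose to 0.111 with limma-voom and to 0.094 with the title prefix as a block in edgeR. In fits added after the data were seen, it was 0.115 without adult replicate 2 and E14.5 replicate 3 and 0.587 without adult replicates 2 and 3, the highest of all alternatives.

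Of 13478 genes tested, 146 differed between the groups, 33 higher and 113 lower in E14.5, which makes 77.4% of them lower. A difference of at least 2-fold was found for 136, of which 31 were higher and 105 lower. The libraries of one group all lay above those of the other for 3252 genes, or 24.1%, where chance gives 10%, and for all 146 called genes. The direction of the 146 held in every fit, which the lack of overlap between the groups made nearly certain in advance. Their count rested on single libraries. It was 3 without E14.5 replicate 1, 3 without adult replicate 3, 38 without adult replicate 1, 46 without adult replicate 2 and 471 without E14.5 replicate 2. DESeq2 called 1425 genes, among them all 146, with 691 higher and 734 lower. Without adult replicate 2 and E14.5 replicate 3, the libraries with the highest endothelial and leukocyte marker levels described below, 36 genes were called, 18 of them among the 146, a fit added after the data were seen. Across the 6 fits without 1 library, only Gm12824, a gene model named after its values were seen, was called in every one, so each gene named as past the test below lost its call without at least 1 library.

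The named genes with the largest increase in E14.5 cultures included a growth inhibitor, matrix genes and a regulator of RNA. Nrk, a protein kinase gene on chromosome X from 138914430 to 139010532, had the largest log2 fold change at 7.03 (SE 1.01, adjusted p = 0.041), from 0.0896 ± 0.0348 to 12.6 ± 9.29 CPM (SD, n = 3 each; edgeR). Cdkn1c, an imprinted gene for a cyclin-dependent kinase inhibitor on chromosome 7 from 143458339 to 143461050, rose by 6.35 on the log2 scale (SE 0.62, adjusted p = 0.022), from 3.69 ± 0.271 to 302 ± 225 CPM. Igf2bp3, which encodes an RNA-binding protein typical of fetal tissue, rose by 4.03 (SE 0.53). Fbn2, the gene for the microfibril protein fibrillin 2, rose by 3.85 (SE 0.49). Dsp, which encodes the desmosome protein desmoplakin, rose by 4.29. The cation channel gene Trpc4 rose by 3.10, the potassium channel gene Kcnk1 by 4.75 and the metalloelastase gene Mmp12 by 4.21. Adjusted p lay between 0.022 and 0.041 for these genes. Mmp12 is known from macrophages, whose markers summed to 353 to 3894 CPM in E14.5 and 30.1 to 236 CPM in adult libraries.

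The named genes with the largest decrease had mean levels of 0.0414 to 1.92 CPM in E14.5 cultures. Fgf7, which encodes keratinocyte growth factor, a fibroblast product that acts on epithelium, fell by 7.65 on the log2 scale (SE 0.53, adjusted p = 0.015). It lies on chromosome 2 from 126034658 to 126091185 and measured 0.176 ± 0.0938 CPM in E14.5 against 36.2 ± 16.2 CPM in adult cultures (SD, n = 3 each; edgeR). Prrx1, a homeobox gene of mesenchyme on chromosome 1 from 163245119 to 163313710, fell by 5.92 (SE 0.60, adjusted p = 0.022), from 44.7 ± 13.3 CPM in adult to 0.737 ± 0.564 CPM in E14.5 cultures. C3, the central complement component, fell by 5.79 (SE 0.68). Fmo2, which encodes a flavin monooxygenase, had 0, 4 and 0 counts in the E14.5 libraries, and its fitted decrease of -8.84 (SE 1.08) is therefore imprecise. The matrix gene Vit, with 2, 4 and 0 counts, had a fitted value of -8.73 (SE 0.82). The metalloreductase gene Steap4 fell by 7.36, the neuritin gene Nrn1 by 7.01, the extracellular superoxide dismutase gene Sod3 by 6.26, the globin gene Cygb by 5.98 and the adhesion receptor gene Gpr133 by 5.65. In adult cultures these 5 genes had mean levels of 12.6, 16.6, 18.6, 13.3 and 24.2 CPM in that order.

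**Figure D2:**
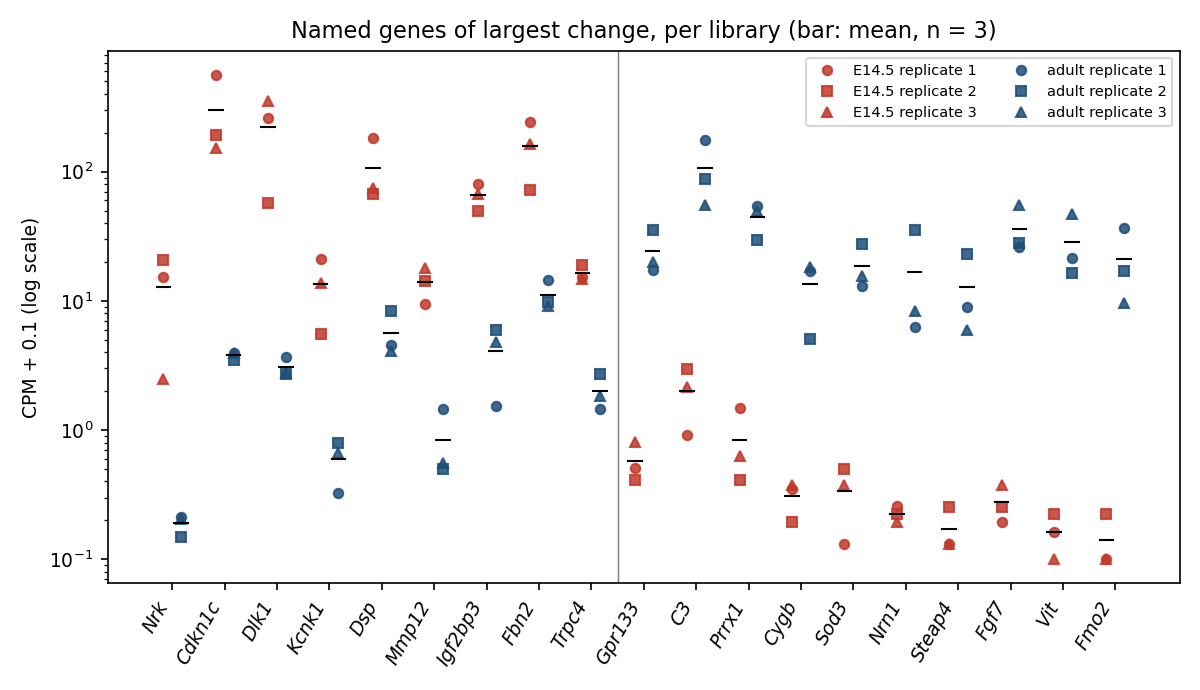
CPM plus 0.1 on a log axis for 9 named genes with a large increase (left) and 10 with a large decrease (right) in E14.5 cultures. Points are single libraries, bars are means of 3, and the groups do not overlap for any of the 19 genes shown, with Dlk1 at 56.7 to 350 CPM in E14.5 and 2.632 to 3.597 CPM in adult libraries.

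By camera with the preset correlation, imprinted genes and genes of fetal tissue were higher as groups in E14.5 cultures. They were among 15 of 38 lists past that test, on which the statements below about groups rest. The other splits of the 6 libraries into 3 and 3, which mix the groups, passed 3 to 15 lists. The number of lists past the test therefore does not set the real split apart. Over the 38 lists, 0 passed with an estimated correlation (3 at an unadjusted p under 0.05). Those 3 were the growth factor, retinoid and Wnt antagonist lists. The estimate lay below the preset 0.01 for the growth factor (-0.0057), retinoid (-0.019) and BMP antagonist (0.0078) lists, and above it for all others of the 15. Correlation among their own members therefore cannot account for the higher unadjusted p of these lists below the preset. Fry called 3, of which the growth factor and retinoid lists are among the 15 and the subepithelial fibroblast list is not. Of 38 tested imprinted genes, 2 rose (Dlk1 and Cdkn1c), 0 fell and 28 had a positive log2 fold change, with a median of 0.42. Adjusted over the list alone, 8 were higher and 2 lower. Camera gave adjusted p = 3.1e-04 with the preset correlation and adjusted p = 0.504 with an estimated correlation. Gnas, the member of highest CPM not past the test, measured 1253 ± 69.3 CPM in E14.5 and 1326 ± 18.6 CPM in adult cultures. Of 20 tested genes of the oncofetal list, 4 rose (Cdkn1c, Dlk1, Igf2bp3 and, named after its values were seen, Igf2bp1) and all 20 had a positive value, with a median of 0.93. Adjusted over the list alone, 9 were higher. Its adjusted p was 2.6e-07 with the preset and 0.504 with an estimated correlation. Nes, the nestin gene, measured 346 CPM in E14.5 and 116 CPM in adults (log2 fold change 1.57, adjusted p = 0.076). Dlk1, Cdkn1c, Igf2 and H19 belong to both lists as set, and Dlk1 may have been chosen on these samples.

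Notch pathway genes did not pass the test as a group. Dlk1 was the only 1 of 25 tested members past the test over all genes, and adjusted over the list alone 2 were higher and 2 lower. The median log2 fold change was -0.17 and the mean 0.20, so these differ in sign, and camera gave a downward adjusted p = 0.507. Jag1, a canonical ligand, measured 204 CPM in E14.5 and 203 CPM in adults, and its log2 fold change of 0.01 (SE 0.34) was within the spread between cultures. Adam10, a sheddase gene, measured 227 and 244 CPM.

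Genes for secreted growth factors were lower as a group in E14.5 cultures. Of 39 tested, 4 fell, among them Fgf7, Angpt2 and, named after its values were seen, Figf, 0 rose, and 29 had a negative value. Adjusted over the list alone, 6 were lower and 0 higher. Angpt2, a ligand of the endothelial receptor TIE2, fell by 5.10 (SE 0.50), and Figf, which encodes a vascular endothelial growth factor, fell by 3.41. Camera gave adjusted p = 0.0039, and adjusted p = 0.504 with an estimated correlation. Endothelial markers summed to 2693 and 787 CPM in adult replicates 2 and 3 and to 45.6 to 240 CPM in the other 4 libraries. Without adult replicates 2 and 3, the median log2 fold change of the growth factor list was -0.29, against -0.36 with all libraries. Between E14.5 replicate 1 and adult replicate 1, which share a title prefix, the log2 difference was -4.09 for Angpt2 and -7.305 for Fgf7. Ctgf, the member of highest CPM, measured 3435 ± 1043 CPM in E14.5 and 4836 ± 528 CPM in adults, which did not pass the test (adjusted p = 0.411).

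The lists of inhibitors of Wnt and BMP signals were lower as groups, with no single member past the edgeR test over all genes. At an unadjusted p under 0.05 there were 4 and 5 members, DESeq2 called 4 and 3, and limma-voom 0 and 1. Among 12 tested Wnt antagonists, 10 had a negative value, and adjusted over the list alone 4 were lower. Their median of -0.68 was -1.54 without E14.5 replicate 3, -1.15 without adult replicate 1 and -1.11 without E14.5 replicate 1. It was -0.49 without E14.5 replicate 2 and -0.46 without adult replicate 3. The list summed to 428, 137 and 509 CPM in E14.5 replicates 1, 2 and 3. In adult replicates 1, 2 and 3 it summed to 315, 622 and 372 CPM, so the groups overlapped in this sum. Among 13 tested BMP antagonists, 10 were negative, and adjusted over the list alone 3 were lower. Their median of -0.46 was -0.85 without adult replicate 2 and E14.5 replicate 3 and -0.35 without adult replicate 3. Fst, the follistatin gene, measured 97.2 ± 102 CPM in E14.5 and 740 ± 526 CPM in adults (adjusted p = 0.184). Adjusted camera p was 0.0019 and 0.028, and adjusted p = 0.504 with an estimated correlation for both. Without E14.5 replicate 2 these adjusted p-values rose to 0.150 and 0.235, and without adult replicate 3 that of the BMP antagonists to 0.051. Wnt ligands and R-spondins (14 tested) and BMP ligands (11 tested) had 0 members past the edgeR test, 2 and 3 at an unadjusted p under 0.05, 3 and 2 in DESeq2 and 0 and 0 in limma-voom, with camera adjusted p of 0.847 and 0.437. Wnt5a measured 227 ± 102 CPM in E14.5 and 91.1 ± 4.06 CPM in adults (log2 fold change 1.31, SE 0.33, adjusted p = 0.121).

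Transcription factors of gut mesenchyme, listed together with Hedgehog response genes, had 2 of 22 tested members past the edgeR test, among them Prrx1, which fell. The list summed to 593, 251 and 564 CPM in E14.5 replicates 1, 2 and 3. In adult replicates 1, 2 and 3 it summed to 566, 540 and 528 CPM, so only E14.5 replicate 2 stood apart. The camera result was downward at adjusted p = 0.045, and adjusted p = 0.775 with an estimated correlation. It rose to 0.740 without E14.5 replicate 2, 0.066 without adult replicate 2, 0.051 without adult replicate 3, 0.072 without both adult replicates 2 and 3, 0.068 with no filter and 0.102 with the stricter filter. Nkx2-3 measured 53.6 and 76.3 CPM in E14.5 and adults (adjusted p = 0.248). None of 28 tested Hox genes passed the edgeR test at an adjusted p of 0.05. Of these, 4 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0, and the median log2 fold change was 0.07 (camera adjusted p = 0.933).

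The complement and retinoid lists were lower as groups in E14.5 cultures. C3 was the only 1 of 14 tested complement genes past the test over all genes, and adjusted over the list alone 7 were lower and 2 higher. The median log2 fold change was -1.32, and it was -2.55 without E14.5 replicate 3 and -2.001 without adult replicate 1. C1s, a protease of the classical pathway, measured 18.2 ± 11.9 CPM in E14.5 and 184 ± 55.1 CPM in adults (log2 fold change -3.34, SE 0.53, adjusted p = 0.055). Among 14 tested retinoid genes, Cyp26b1, which encodes an enzyme that degrades retinoic acid, fell by 4.61 (SE 0.33, adjusted p = 0.015), from 234 ± 30.3 CPM in adult to 9.56 ± 3.63 CPM in E14.5 cultures. Adjusted over the list alone, 6 retinoid genes were lower and 1 higher. Aldh1a1, for an enzyme that makes retinoic acid, measured 277 ± 98.1 and 680 ± 57.5 CPM in E14.5 and adults (adjusted p = 0.098). Both lists had camera adjusted p = 0.0055, and adjusted p = 0.504 with an estimated correlation. That of the retinoid list rose to 0.119 without E14.5 replicate 2. Complement genes summed to 457, 381 and 520 CPM in E14.5 replicates 1, 2 and 3 and to 825 to 932 CPM in adult libraries. Retinoid genes summed to 543, 595 and 805 CPM and to 1552 to 2028 CPM in the same order, so the groups did not overlap in either sum. Mesothelial markers summed to 398 and 346 CPM in E14.5 replicates 1 and 3 and to 1077 to 2608 CPM in E14.5 replicate 2 and the adult libraries. E14.5 replicate 2 thus lay with the adult libraries in mesothelial markers but not in the complement or retinoid sums.

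Chemokine, cytokine and acute-phase genes moved in both directions by list-wise adjustment. Of 36 tested, 3 fell, with log2 fold changes of -2.04 for Ccl7, -2.82 for Ccl2 and -3.25 for Il34, and 0 rose. Adjusted over the list alone, 10 were lower and 6 higher. Camera was downward at adjusted p = 0.023, and adjusted p = 0.504 with an estimated correlation. It rose to 0.144 without E14.5 replicate 1 and to 0.055 without both adult replicate 2 and E14.5 replicate 3, and the median of -0.33 was -0.0456 without adult replicate 3 and -1.15 without E14.5 replicate 2. Ccl2 and Ccl7 attract monocytes, and Il34 is a ligand of the macrophage receptor CSF1R. Macrophage and leukocyte markers, at 353 to 3894 CPM in E14.5 and 30.1 to 236 CPM in adult libraries, lay the other way. Csf1, another ligand of that receptor, measured 987 ± 827 and 2318 ± 383 CPM in E14.5 and adults (adjusted p = 0.340).

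Matrix genes changed in both directions. Among 50 tested genes of interstitial matrix, Fbn2 rose, Fmod fell by 4.37 (SE 0.51) and Col6a1, a chain of collagen VI, fell by 2.54 (SE 0.36). Adjusted over the list alone, 4 were higher and 11 lower, and 33 of the 50 had a negative value. Camera was downward at adjusted p = 0.030, and adjusted p = 0.775 with an estimated correlation. It rose to 0.129 without adult replicate 1, 0.128 without adult replicate 3 and 0.740 without E14.5 replicate 2. The median of -0.30 was -0.10, -0.17 and -0.16 in these fits. It was -0.54 without adult replicate 2 and E14.5 replicate 3 and -0.46 without adult replicates 2 and 3. Fn1 measured 14881 ± 875 CPM in E14.5 and 11863 ± 2259 CPM in adults (adjusted p = 0.488). None of 27 basement membrane genes passed the edgeR test at an adjusted p of 0.05, where 10 had an unadjusted p under 0.05, DESeq2 called 7 and limma-voom 0 (camera adjusted p = 0.412). Of 29 tested proteases and inhibitors, Mmp12 alone did (camera adjusted p = 0.872).

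Fibroblast identity genes differed in part. Pdgfra, the receptor that marks subepithelial fibroblasts when highly expressed, fell by 3.72 (SE 0.50, adjusted p = 0.036), from 47.4 ± 29.1 CPM in adult to 3.59 ± 1.01 CPM in E14.5 cultures, as the only 1 of 14 tested genes of its list (camera adjusted p = 0.406). With p adjusted over the list alone, 3 were higher and 2 lower. Of 18 tested markers of crypt-base fibroblasts positive for CD81 or CD34, C3 fell, and adjusted over the list alone 5 were lower and 0 higher. Camera was downward for that list at adjusted p = 0.0032, and adjusted p = 0.504 with an estimated correlation. The median log2 fold change of -0.53 was -1.09 without E14.5 replicate 3. Without E14.5 replicate 2 the median was -0.12, and the adjusted camera p with the preset correlation rose to 0.145. The list summed to 1958 CPM in that library, to 4858 and 6482 CPM in E14.5 replicates 1 and 3 and to 3225 to 4851 CPM in adult libraries. Cd81 itself measured 786 and 761 CPM. Smooth muscle contractile genes were abundant in both groups. Acta2, the smooth muscle actin gene, measured 12918 ± 2828 CPM in E14.5 and 12812 ± 3594 CPM in adults, and 0 of 29 members passed the edgeR test (6 at an unadjusted p under 0.05, 4 in DESeq2, 0 in limma-voom, camera adjusted p = 0.933). Igfbp7 fell by 1.504 (SE 0.21), the only 1 of 15 tested genes of the IGF axis past the test (camera adjusted p = 0.289), and Scd1, a fatty acid desaturase gene, fell by 0.81 (SE 0.12) among 26 lipid genes. On adjustment within each list, 3 genes of the IGF axis were higher and 3 lower, and 4 lipid genes were higher and 6 lower.

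Ribosomal protein genes were slightly higher in E14.5 cultures as a group. The median log2 fold change over 74 tested genes was 0.32, and 73 were positive, but 0 passed the edgeR test over all genes or over the list alone, with 44 at an unadjusted p under 0.05, 22 called by DESeq2 and 0 by limma-voom. Camera gave adjusted p = 1.6e-15, and adjusted p = 0.504 with an estimated correlation. Rplp0 measured 1109 ± 116 CPM in E14.5 and 860 ± 39.4 CPM in adults (adjusted p = 0.232). Genes of S phase and mitosis had 0 of 44 members past the edgeR test, 2 at an unadjusted p under 0.05, 1 in DESeq2 and 0 in limma-voom, and camera adjusted p = 0.289. Camera adjusted p was 0.437 for cell cycle inhibitors, 0.060 for interferon genes, 0.105 for TGF-beta response, 0.060 for lipid genes, 0.933 for hypoxia genes, and 0.226 for dissociation and immediate early genes. Median and mean log2 fold changes differed in sign for Wnt ligands (0.28 and -0.09), BMP ligands (0.08 and -0.46), contractile genes (-0.12 and 0.18), proteases (-0.17 and 0.28), hypoxia genes (0.04 and -0.17), pericyte markers (-0.35 and 0.47) and sex-linked genes (-1.09 and 2.07). Camera had the sign of the median in these lists except the BMP ligands, where it was downward.

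**Figure D3:**
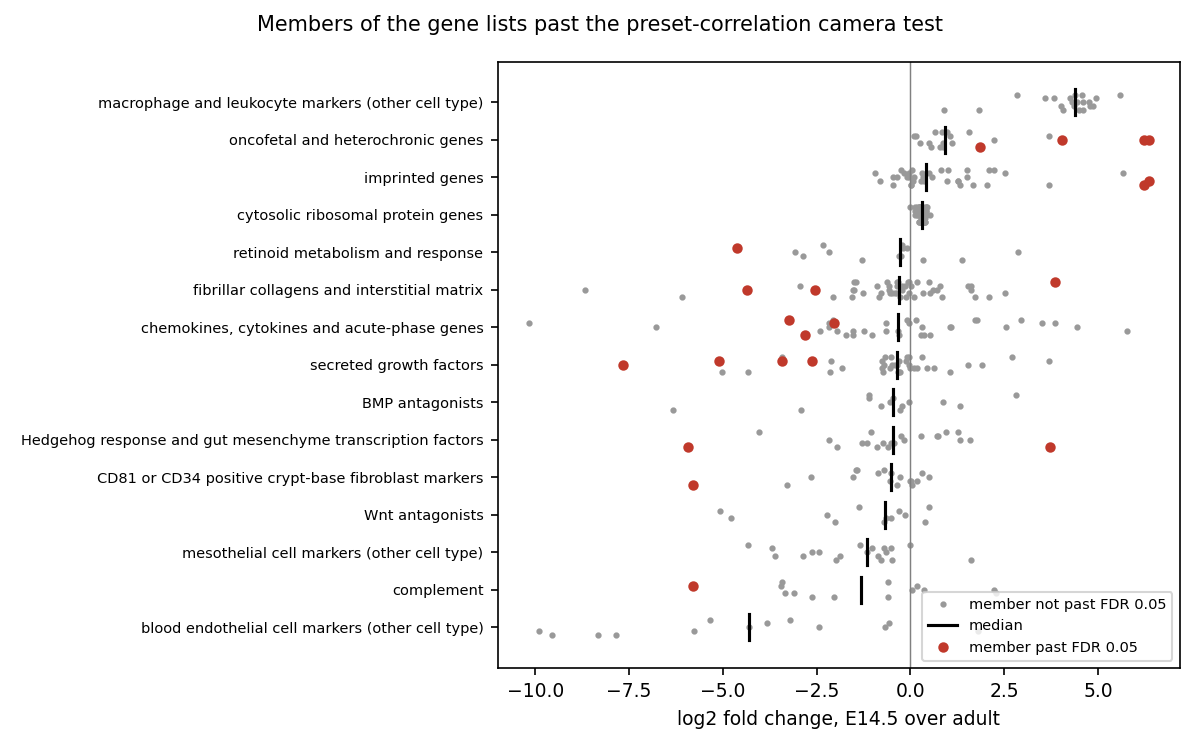
Log2 fold change, E14.5 over adult, of each tested member of the 15 gene lists past the camera test with a preset correlation. Points are genes, red for an adjusted p under 0.05, and black bars are list medians, from -4.29 for blood endothelial markers to 4.38 for macrophage and leukocyte markers.

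Markers of other cell types differed between libraries. Macrophage and leukocyte markers summed to 353, 591 and 3894 CPM in E14.5 replicates 1, 2 and 3, and to 236, 30.1 and 62.0 CPM in adult replicates 1, 2 and 3. All 21 tested members were positive (median 4.38, and 2.62 without E14.5 replicate 3), 0 passed the edgeR test over all genes and 19 did so adjusted over the list alone, with 19 at an unadjusted p under 0.05, 15 called by DESeq2 and 0 by limma-voom (camera adjusted p = 2.5e-11, and adjusted p = 0.504 with an estimated correlation). Lyz2 measured 766 CPM in E14.5 replicate 3. Blood endothelial markers summed to 2693 CPM in adult replicate 2 and 787 CPM in adult replicate 3, against 240 CPM in adult replicate 1 and 45.6 to 157 CPM in E14.5 libraries. Of 13 tested members, 0 passed the edgeR test over all genes and 9 were lower in E14.5 adjusted over the list alone, with 9 at an unadjusted p under 0.05, 8 called by DESeq2 and 0 by limma-voom (camera adjusted p = 8.0e-05, and adjusted p = 0.504 with an estimated correlation). Emcn measured 1073 CPM in adult replicate 2 and 2.39 CPM in adult replicate 1. Mesothelial markers summed to 398, 1393 and 346 CPM in E14.5 and 2608, 1077 and 1499 CPM in adult replicates 1, 2 and 3, and 18 of 19 tested members had a negative log2 fold change, with 0 past the edgeR test, 6 at an unadjusted p under 0.05, 5 in DESeq2 and 0 in limma-voom (camera adjusted p = 8.0e-05, and adjusted p = 0.600 with an estimated correlation). Epithelial, lymphatic endothelial, neuronal, glial, interstitial cell of Cajal and pericyte markers did not pass, with camera adjusted p from 0.437 to 0.764. Without adult replicates 2 and 3, the camera adjusted p of the endothelial list rose to 0.067 and its median of -4.29 became -0.68, where it was -6.54 without E14.5 replicate 1. Only 2 erythroid markers could be tested.

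**Figure D4:**
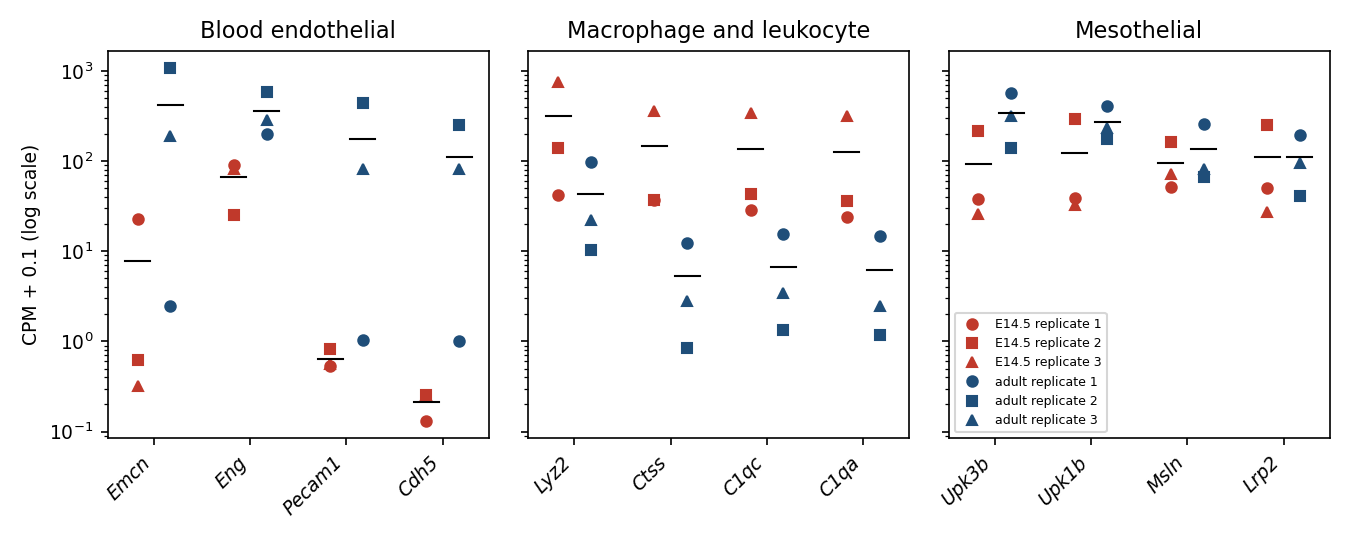
CPM plus 0.1 on a log axis for the 4 highest-CPM blood endothelial, macrophage and leukocyte, and mesothelial markers. Points are single libraries and bars are group means of 3, with Emcn at 1073 CPM in adult replicate 2 and 2.39 CPM in adult replicate 1.

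Transcripts of the sex chromosomes were also measured. Xist, the RNA of the inactive X chromosome, measured 200, 33.3 and 141 CPM in E14.5 replicates 1, 2 and 3 and had 0 counts in all adult libraries. It was at least 1015-fold higher in E14.5, taking 3 counts per adult library as a floor, with an adjusted p = 0.051. The list of sex-linked genes (5 tested) had 0 members past the edgeR test, 1 at an unadjusted p under 0.05, 1 in DESeq2 and 0 in limma-voom, and camera adjusted p = 0.679. The Y-linked gene Ddx3y measured 14.1, 124 and 78.3 CPM in the E14.5 libraries and 166, 147 and 173 CPM in the adult libraries. Each E14.5 library thus held both Xist and a Y-linked transcript, and the adult libraries held the Y-linked transcript without Xist. Sex-linked expression therefore differed together with stage, and effects of sex and stage on other genes cannot be separated here.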

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

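These values were picked out after the counts were seen, and no test was run on them. Signal appeared in the forward-strand counts, which no comparison above uses. Over the 6 libraries, Myo1h had 36241 forward-strand counts against 478 reverse-strand counts, and Krr1 had 34813 against 4303, far above the 3 counts that a true 0 allows. In GENCODE release M21, Myo1h (chromosome 5, 114289166 to 114365357, plus strand) overlaps the protein-coding gene Kctd10 on the minus strand, and Krr1 (chromosome 10, 111972664 to 111988432, plus strand) overlaps Glipr1 on the minus strand. Of 5722 genes with more than 3 forward-strand counts in every library, 460 had more forward-strand than reverse-strand counts.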

How the results depend on the processing

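The fits with the unstranded column and those without a pair of libraries were chosen after seeing the data. Counts of genes rested on the tool and on single libraries. The 146 genes (136 at 2-fold) stayed within 1.5 times under every scaling and filter and with limma-voom and the unstranded column. DESeq2 gave 1425 (1044 at 2-fold). In simulation 31.6% of its calls were false, against 7.21% for edgeR, but the cause of the gap was not tested. Each draw changed 200 of 13478 genes, and the share of false calls depends on how many genes change. These shares therefore need not hold for the real calls. An adjusted p of 0.01 left 2 genes and a test against 2-fold left 18. Fits without 1 library gave 3 to 471 genes (3 to 419 at 2-fold), and 1 gene was called in all 6 of them. Leaving out adult replicate 2 and E14.5 replicate 3 gave 36 and 36, with fewer libraries. Leaving out adult replicates 2 and 3 assumes that the lone adult library varies like the E14.5 ones and gave 0 and 0 in edgeR, with 842 genes at an unadjusted p under 0.05. No other tool was run there.

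The replicate block by title prefix called 2 genes (2 at 2-fold). Libraries with the same prefix deviated from their group means with correlations of -0.141, -0.229 and -0.088. No E14.5 library correlated best with its own prefix, and the prefix was not taken to pair them. With 3 libraries per group, deviations from the mean offset each other, so these correlations cannot exclude a pairing. Dlk1 had a log2 fold change of 5.92 with the block (adjusted p 0.094), 5.87 with limma-voom, 5.66 without the most endothelial and leukocyte libraries, 5.94 without both endothelial adult libraries and 5.74 to 6.68 without 1 library. Its adjusted p over alternatives ran from 3.6e-24 to 0.587.

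Of 38 lists, 15 passed camera, and 10 to 18 did so without 1 library. With an estimated correlation 0 of 38 passed (smallest adjusted p 0.504), and fry called 3, of which 2 are among the 15. The causes were not tested, but the correlation was estimated below the preset 0.01 for the growth factor, retinoid and BMP antagonist lists. The Hedgehog list lost its call in 7 of 15 fits, the block among them (adjusted p 0.072), and the interstitial matrix list in 3.

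Of 510 refits of 30 other named genes past the test, 297 kept direction and call, 213 kept direction only and 0 reversed. The groups do not overlap for any of these genes, which made a reversal unlikely in advance. Of 1257 refits of 74 named genes not past it, 1171 kept direction and side of the test, 31 kept direction and passed it, and 55 changed sign. Without 1 library, log2 fold changes ran from -0.0898 to 0.20 for Cd81, -0.18 to 0.0493 for Adam10, -0.23 to 0.42 for Jag1, -0.18 to 0.72 for Rspo3, -1.27 to 0.59 for Sfrp1, -0.22 to 0.44 for Inhba, -1.20 to 0.00551 for Bmp4, -0.39 to 0.0107 for Fstl1, -0.11 to 0.64 for Igfbp3, -0.21 to 0.17 for Acta2, -0.0537 to 0.96 for Dcn, -0.14 to 0.27 for Ccng1, -1.23 to 0.79 for Ptgs2, -0.40 to 0.0379 for B2m, -0.0716 to 0.35 for Scd2, -0.11 to 0.37 for Pkm2, -0.0659 to 0.19 for Aldoa, -0.16 to 0.22 for Hsp90aa1, -0.33 to 0.30 for Fabp7, -0.50 to 0.0284 for Gja1, -0.0434 to 0.47 for Tfrc and -1.38 to 0.0227 for Epor. With limma-voom, Dkk3 was at -0.0371, Ptgs2 at -0.29 and Hsp90aa1 at -0.00025, and with the block Ptgs2 was at -0.62. Without both endothelial adult libraries, Cd81 was at -0.22, Adam10 at 0.0393, Sfrp1 at 1.26, Inhba at -0.17, Bmp4 at 0.50, Igfbp3 at -0.15, Acta2 at -0.22, Ccng1 at -0.17, Ptgs2 at -0.62, Pkm2 at -0.15, Aldoa at -0.0213, Emcn at 1.70, Flt4 at 1.28 and Fabp7 at 0.27. Without adult replicate 2 and E14.5 replicate 3, Adam10 was at 0.0431, Rspo3 at -0.14, Acta2 at -0.0494, Dcn at -0.29, Scd2 at -0.13 and Fabp7 at 0.0109. The cause was not tested.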

Other observations

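The tests in this part were chosen after the result was seen, except those of other splits of the libraries and of the share of called genes on X or Y. Frizzled receptors, which bind Wnt ligands, were singled out after their values were seen. Of 9 tested, Fzd4, Fzd5 and Fzd8 were lower in E14.5 cultures, with log2 fold changes of -1.88 (SE 0.25), -1.78 (SE 0.21) and -1.18 (SE 0.17) and adjusted p of 0.036, 0.033 and 0.041 in edgeR. Fzd5 measured 18.1 ± 3.28 CPM in E14.5 and 62.1 ± 13.8 CPM in adults. Fzd1 had the largest change the other way and did not pass the edgeR test (log2 fold change 1.22, SE 0.50, adjusted p = 0.279). The most abundant member, Fzd7, measured 268 ± 115 and 227 ± 37.5 CPM (adjusted p = 0.786).

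Some other genes past the edgeR test were also singled out after their values were seen, from no list. Gpr50 was higher in E14.5 (log2 fold change 5.95, SE 0.43), as were Grik2, a glutamate receptor gene (4.95, SE 0.50), and Epha7, an ephrin receptor gene (2.89, SE 0.37). Calca, the gene for calcitonin gene-related peptide (-6.54, SE 0.66), Cck, the cholecystokinin gene (-4.00, SE 0.55), and Avpr1a, a vasopressin receptor gene (-2.98, SE 0.16), were lower.

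The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 146 genes, and the highest of the other splits gave 0, so 1 of the 10 reached that count. For genes changed at least 2-fold, the real split gave 136 and the others at most 0. For gene lists past camera with a preset correlation, the other splits passed 3 to 15. The real count of 15 was thus reached by 2 of the 10 splits, the real one and 1 other. That other split set adult replicates 1 and 3 with E14.5 replicate 1 against the rest, and it gave 0 genes in edgeR.

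Blood endothelial markers stood high in adult replicates 2 and 3 alone. In E14.5 replicates 2 and 3, which carry the same title prefixes, 0% of the 13 tested markers were at least 4-fold above E14.5 replicate 1 in both. This argues against a shared preparation that raised the markers in both tissues alike. The tissues were handled differently before digestion, so a preparation that acted on adult tissue alone stays open. Endothelial cells carried in the adult cultures may account for the high markers. In both adult libraries 69.2% of the markers, 9 of 13, were at least 4-fold above adult replicate 1. That is short of the 80% set as needed, a limit set after the data were seen. Among abundant markers, Emcn measured 1073 and 191 CPM there against 2.39 CPM in adult replicate 1. Pecam1 measured 444 and 81.5 against 0.946 CPM, and Cdh5 255 and 82.0 against 0.909 CPM. Eng, which rose less than 4-fold to 584 and 289 CPM, was already at 202 CPM in adult replicate 1. The missed limit therefore does not by itself argue against endothelial cells. None of the 13 is in another list, no sort that would remove endothelial cells is named in the labels, and this explanation, like a difference between the adult donors, stays open.

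On the first principal component, E14.5 replicate 2 (34.39) lay nearer to the adult libraries than E14.5 replicates 1 (56.38) and 3 (77.83), and it had the lowest Dlk1 of its group. If adult material alone lowered Dlk1 there, its share would be 81.5%. Genes were taken that had at least 10 CPM in every adult library and were at least 8-fold lower in E14.5 replicates 1 and 3. These 37 genes had a median of 7.90% of the adult mean in E14.5 replicate 2 (quartiles 2.49% and 31.0%). This argues against adult material at the share that Dlk1 implies, while a smaller share was not tested. A lower share of cells with embryonic transcripts may account for the low Dlk1 and the position of that library, but stays open. The 33 genes called higher in E14.5 had a median log2 difference of -0.38 in replicate 2 against the mean of the other E14.5 libraries (quartiles -0.61 and -0.10). That is far from -2.43 for Dlk1, with Trpc4 at 18.99 CPM against 15.29 and 14.71 CPM, although calling favours genes of small spread. A choice that favours low values in the left-out library, 27 genes of at least 10 CPM and 8-fold above every adult library in E14.5 replicates 1 and 3, gave -2.67 in replicate 2, where the same choice gave 1.20 for replicate 1 (9 genes) and -0.34 for replicate 3 (11 genes). More mesothelial-like cells are a candidate source, since 84.2% of the 19 tested mesothelial markers, 6 of them also in another list, were at least 2-fold above the mean of the other E14.5 libraries, with Upk3b at 216 CPM and Upk1b at 296 CPM, and a difference in embryo age or gut region stays untested.

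Xist was present in all 3 E14.5 libraries and in no adult library. Of the 145 called genes with a known chromosome, 4.14% lie on X or Y, against 3.46% of 13343 tested genes (Fisher's exact test, two-sided, p = 0.643). This argues against genes on X or Y as the source of most called genes. Autosomal genes can also differ by sex, and sex-linked expression differed together with stage, so an effect of sex on them stays open. E14.5 cultures made from embryos of both sexes may account for Xist beside Y-linked transcripts, which all 3 E14.5 libraries held. The median level of 4 Y-linked genes was 8.49%, 65.9% and 61.1% of the adult mean in E14.5 replicates 1, 2 and 3. Single Y-linked genes stood at 7.75% to 88.4% of the adult mean in these libraries. Xist per remaining share differed 3.70-fold between the libraries, beyond the 3-fold set as a limit. With single Y-linked genes it differed 1.47-fold to 6.99-fold, so the 4 genes are too few to decide on this ratio. The ratio asks only whether Xist followed the share without Y-linked transcripts. It does not test whether cells of both sexes were present, which Xist beside Y-linked transcripts in every E14.5 library would reflect.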
